A study of Rattus norvegicus with 8 samples.

How the data were processed

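Total RNA of the thoracic aorta from 4 control Wistar and 4 diabetic GK rats was sequenced, and the samples were grouped by the titles, strain and group given in the labels. The source name of every sample reads GK, controls included, and was not used. The authors deposited raw counts per gene and per lncRNA transcript, whole numbers in columns named count per the file headers. FPKM values per library and as group means are in the same files per the file headers; across the 8 libraries the denominator behind the gene FPKM was checked to follow the total gene counts, and FPKM was not used for any test. The log2 fold changes deposited by the authors are of those group means, with infinite values where a mean is 0. The authors' p-values and q-values come from edgeR per the file headers and names, with no version or test given. The calls in the authors' deposited table equal a q-value under 0.05 with at least a 2-fold change. The numbers of genes per term or pathway, called and annotated, are the authors' deposited enrichment values per the file headers, with all annotated genes as background. The pairs of lncRNA and target gene are the authors' own prediction, with no tool or distance given in the sources used here. Per the submitters' processing notes the tools include Bowtie 0.12.2 and the builds mm8 and mm9, which are mouse builds and have no role stated. The rat build is not given in the sources used here, so coordinates are printed as the files give them. Gene symbols came from the files, and 2 list genes were matched through synonyms in the rat reference table (assembly GRCr8), none of whose coordinates were used.

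From the counts, CPM, log2 fold changes and tests were computed in R 4.3.3. Genes were tested with edgeR 4.0.16 (filterByExpr on the 2 groups, TMM factors, glmQLFit and glmQLFTest, group as the only term) at a Benjamini-Hochberg adjusted p under 0.05, without a fold minimum. The lncRNA table was tested in the same way with its own totals and factors. Library totals ran from 11760397 to 16266151 for genes and from 1185872 to 2031376 for lncRNA, and TMM factors for genes from 0.825 to 1.24. CPM in the text are counts over the table's library total times its TMM factor, and floors and ratios use the same totals. SE is the log2 fold change over the root of the quasi-likelihood F. Where a group had 0 counts, the fold is a lower bound from 3 counts over the group, and with 1 to 3 counts the ratio has a 95% counting interval.

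Before the data were examined, 46 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were contractile smooth muscle, synthetic smooth muscle, endothelial, fibroblast, macrophage, T cell, B and plasma cell, neutrophil, mast cell, brown adipocyte, general adipocyte, skeletal muscle, cardiomyocyte, erythroid, nerve and Schwann cell, mesothelial and epithelial, lymphatic endothelial, sex-linked, lipogenesis, cholesterol synthesis and uptake, fatty acid oxidation, glycolysis, insulin signalling, renin-angiotensin-aldosterone, nitric oxide and cGMP, endothelin and prostanoid, calcium and potassium handling, collagens, elastic fibre and matrix glycoproteins, matrix proteases and inhibitors, TGF-beta pathway, osteochondrogenic and calcification, inflammatory adhesion and cytokine, interferon-stimulated, major histocompatibility complex and antigen presentation, complement, oxidative stress and NADPH oxidase, unfolded protein response, immediate early and heat shock, circadian clock, glucocorticoid-responsive, hypoxia, cell cycle, nuclear-encoded respiratory chain, mitochondrially encoded, cytosolic ribosomal protein. They listed 769 members, of which 741 were found, and 677 distinct genes were tested. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), two-sided, adjusted over 44 lists; camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance, not against other genes. Members past the test were counted over all genes and adjusted over the list alone. Named genes were the 10 with the largest rise and the 10 with the largest fall among changed genes with a log2 CPM of at least 1, no overlap of the groups and a gene symbol that is not of a clone type. To these came up to 3 changed members of each list with the lowest adjusted p, or, with none, the 2 with the highest mean CPM. For lncRNA the 5 largest rises and falls under the same limits were named, and for pairs the 5 with the lowest larger adjusted p, 1 per lncRNA. Of each enrichment table the 5 terms with the lowest adjusted p are given. The authors' adjusted p-values do not always rise with their unadjusted ones, so terms with a lower unadjusted p can be absent.

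The share of pairs with the same sign was tested two-sided by permuting fold changes over lncRNAs (100000 resamples, 10000 in the alternatives). List means, and the SD of the group differences over the class II genes, were compared by exact permutation over the 35 splits of the 8 libraries into 4 and 4. The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, edgeR's exact test, no filter, a mean CPM of at least 1, a 2-fold minimum, the replicate number as a block, counts summed per symbol, gene-table totals for lncRNA, and each library left out. After the data were seen, leaving out both libraries numbered 9, the fat score as a covariate, leaving out mitochondrial genes and leaving out pairs whose lncRNA and gene overlap were added. The fat score is the mean log2 CPM of the brown and general adipocyte lists.

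The fits were tested on simulated data. Of 100 genes changed 2-fold 19 were recovered and of 100 changed 4-fold 91, with 5 of 115 calls false (13544 genes run). For lncRNA, 5 of 93 changed 2-fold and 61 of 97 changed 4-fold were recovered, with 5 of 71 calls false (11146 run). A collagen list lowered 2-fold was found by camera and 0 other lists of 44 were called (13673 genes run). The simulated genes were drawn independently, whereas the correlation estimated in the data was 0.60 for collagens and 0.51 for elastic fibre genes. The simulation therefore does not show how often camera calls a list falsely when its genes move together. Circular RNA itself and the tables of broad term classes were not analysed here. Some genes that these rules select, and a test that needs one of them, are not reported here.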

Results

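RNA of the thoracic aorta was sequenced from Goto-Kakizaki (GK) rats, a strain with inherited non-obese diabetes, and from Wistar rats as controls, all 7 to 8 weeks old. Each group had 4 libraries, which share the numbers 7 to 10. The gene table held 19238 genes and the table of long non-coding RNA (lncRNA) 24300 transcripts. Total gene counts per library were 13466170, 11760397, 12052916 and 13415685 in controls 7 to 10 and 16266151, 14988116, 13188728 and 16033231 in GK 7 to 10. The lncRNA totals lay between 1185872 in control 8 and 2031376 in control 10. Strain and diabetes were the same split of the samples, so no value below separates them. Beyond the titles, nothing in the labels says that the libraries are separate animals, so each p-value measures the spread between these samples only. CPM values are means ± SD of 4 libraries per group, log2 fold changes are GK over control ± SE (n = 4 per group), and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

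Which genes differ in the aorta of the diabetic strain was the first question. Genes of very different kinds stood at the top of the change. Orm1, an acute-phase plasma protein, had 1 count in the controls and 501 in the GK libraries, a CPM ratio of 475 with a counting interval of 84.8 to 18785. Tmem179, a membrane protein gene, had 0 counts in the controls and was at least 79.4-fold higher in GK (floor of 3 counts over the group; 12.1 CPM in GK 9 against 2.61 or less in the other GK libraries, so GK 9 sets most of it; edgeR adjusted p = 0.0368). Ifit1, an interferon-induced antiviral gene, rose from 0.300 ± 0.157 to 42.1 ± 53.4 CPM, with 122 CPM in GK 10 alone. Slc24a2, a sodium, potassium and calcium exchanger on chromosome 5 (105336262 to 105582375; the build of these coordinates is not given in the sources used here), rose by 5.62 ± 0.36 on the log2 scale (edgeR adjusted p = 8.95e-04). Ush1c, a scaffold protein of hair cells and gut epithelium, rose by 6.88 ± 0.97, the imprinted gene Magel2 by 6.35 ± 0.79, and Adtrp, a lipid hydrolase, by 5.10 ± 0.59. Mfsd2a, the lysophosphatidylcholine transporter, rose by 5.67 ± 1.04. It stood at 9.66 CPM in GK 7 against 2.61 or less in the other GK libraries, and among controls only control 9 had counts. The N-type calcium channel gene Cacna1b rose by 5.03 ± 1.03 (35.8 CPM in GK 9, 5.85 or less in the other GK libraries) and Glod5 by 5.03 ± 0.72.

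Among the genes that fell, Gcgr, the glucagon receptor, went from 23.3 ± 19.7 to 0.188 ± 0.138 CPM (log2 fold change -6.86 ± 0.94, edgeR adjusted p = 0.00946). Eln, the gene of elastin, fell from 4309.8 ± 2574 to 329 ± 147 CPM, a log2 fold change of -3.71 ± 0.57. Scd1, the stearoyl-CoA desaturase, fell from 954 ± 1013 to 34.5 ± 32.9 CPM. It stood at 2423 CPM in control 9 against 785 or less in the other controls, and at 83.8 in GK 9 against 18.1 or less in the other GK libraries. Complement C3 fell by 4.36 ± 0.73 on the log2 scale, RT1-CE10, a class I gene of the rat major histocompatibility complex, changed by -4.51 ± 0.31, and RT1-Ba, a class II gene, by -4.12 ± 0.60. Crabp2, which carries retinoic acid, changed by -4.06 ± 0.54 and the orphan transporter Slc16a14 by -4.22 ± 0.91. In control 9 Slc16a14 stood at 86.5 CPM and Crabp2 at 9.34, against 18.2 and 4.27 or less in the other controls. L3mbtl4 changed by -3.99 ± 0.78 and Sytl5, a vesicle-traffic gene, by -3.76 ± 0.59. Of 13673 genes tested by edgeR, 995 changed, 542 higher and 453 lower in GK, and 631 of them by at least 2-fold. The groups did not overlap for 2129 genes, 15.6% of those tested against 2.86% expected by chance, and for 960 of the 995. Genes are not independent, so this excess by itself does not exclude chance. Single libraries moved the count. It was 135 without control 10, 180 without GK 8, 187 without GK 7, 294 without GK 10, 520 without control 9, 567 without control 7, 591 without control 8 and 3047 without GK 9. Leaving out both libraries numbered 9, chosen after the data were seen, gave 2532 genes.

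**Figure D1:**
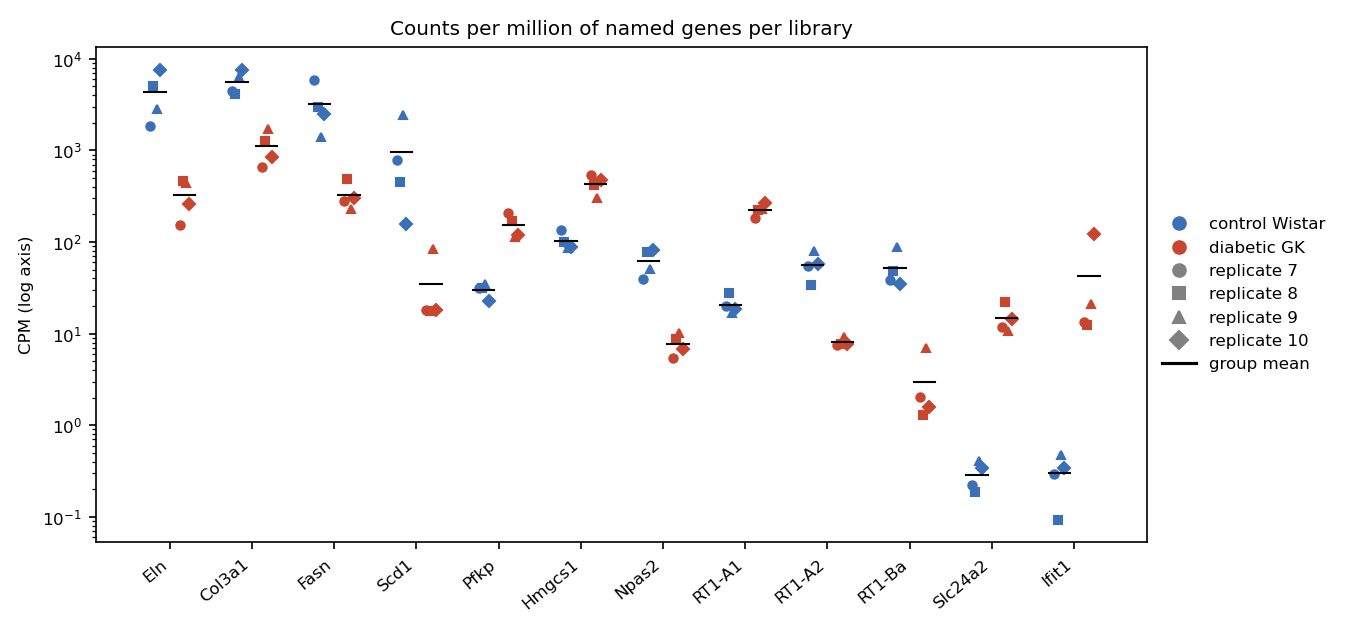
CPM (log axis) of 12 named genes in each library, with control Wistar in blue, diabetic GK in red, a marker shape per replicate number and a line at the group mean (n = 4 per group). The groups do not overlap for any of the 12, nor for 960 of all 995 changed genes. The naming rule required this of Eln, Scd1, RT1-Ba, Slc24a2 and Ifit1. RT1-A1 and RT1-A2 move in opposite directions, from 20.7 to 224 CPM and from 56.5 to 8.05 CPM.

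Genes of the matrix, of smooth muscle and of fibroblasts were lower in GK as lists. In the list of elastic fibre and matrix glycoprotein genes, 8 of 19 tested members fell and none rose (12 fell adjusted over the list alone), with a median log2 fold change of -1.14. Lox, which cross-links elastin and collagen, fell from 347 ± 148 to 38.6 ± 16.0 CPM, and Sparc, a collagen-binding matrix protein, from 3746 ± 1302 to 803 ± 136 CPM. Of 17 collagen genes 8 fell (9 adjusted over the list alone, where Col12a1 rose), with a median of -1.12. Col3a1, a fibrillar collagen, went from 5641 ± 1668 to 1122 ± 467 CPM (edgeR adjusted p = 0.0172), Col4a5 of the basement membrane changed by -2.30 ± 0.39 and Col5a2 by -1.54 ± 0.31. By camera the elastic fibre list had an adjusted p of 3.40e-07 and the collagens 6.53e-05, and each had adjusted p = 0.716 with an estimated correlation. Contractile smooth muscle genes had a median of -0.99, and 3 of 20 fell, also adjusted over the list alone: Itga8, an integrin of smooth muscle (-2.21 ± 0.39), Kcnmb1, a potassium channel subunit (-1.86 ± 0.42), and Lmod1, an actin nucleator (-1.37 ± 0.32). Synthetic smooth muscle genes had a median of -0.65, with 1 of 14 lower (5 adjusted over the list alone): Mgp, the inhibitor of calcification, fell to 59.7 ± 19.8 CPM from 329.9 ± 103. Fibroblast genes had a median of -1.20, and 3 of 13 fell (9 adjusted over the list alone), namely Mmp2, a gelatinase (-1.82 ± 0.34), Dpt, dermatopontin (-2.15 ± 0.45), and Cd34 (-0.85 ± 0.20). Camera adjusted p-values were 1.01e-04, 0.0116 and 3.16e-05 for these lists, each with adjusted p = 0.716 with an estimated correlation.

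Fat genes stood higher in GK where these lists stood lower. The mean log2 CPM of the adipocyte lists (fat score) was 7.94, 8.23, 7.23 and 7.50 in controls 7 to 10 and 8.94, 8.90, 7.90 and 8.96 in GK 7 to 10, so GK 9 lay below controls 7 and 8. In control 9, with the lowest score, brown adipocyte genes averaged 4.78, against 5.92 to 6.77 in the other controls. Its general adipocyte genes averaged 8.98, within the 8.64 to 9.26 of the other controls. The score therefore need not measure the amount of fat alone. With that score as a covariate, an alternative chosen after the data were seen, the camera calls of these lists ended. Adjusted p was then 0.101 for elastic fibre, 0.579 for collagens, 0.646 for contractile smooth muscle and 0.769 for fibroblast genes. For synthetic smooth muscle genes camera then pointed up while the median stayed below 0 (-0.19, adjusted p = 0.540). The synthetic list also lost its call without control 9 (adjusted p = 0.0681). Related lists were not called by camera. Of 15 matrix proteases and inhibitors 1 fell, Mmp14, a membrane-bound collagenase (-1.36 ± 0.30). Adjusted over the list alone 3 rose and 3 fell (median -0.44, camera adjusted p = 0.540). In the TGF-beta pathway 1 of 17 genes fell, also adjusted over the list alone, the ligand Tgfb3, from 239 ± 104 to 61.1 ± 21.9 CPM (list median -0.10, camera adjusted p = 0.152). Of 9 osteochondrogenic and calcification genes 1 fell (2 adjusted over the list alone), Bmp4, a bone morphogenetic protein (-1.55 ± 0.36; list median -0.47, camera adjusted p = 0.216).

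**Figure D2:**
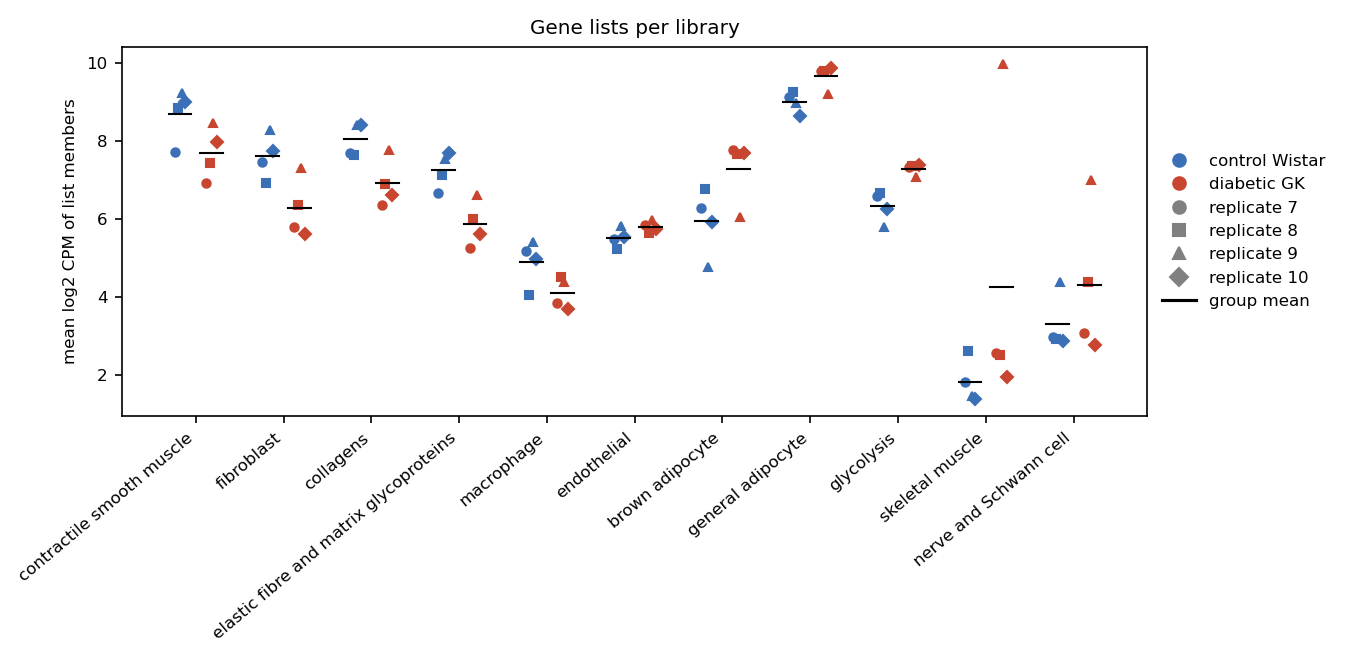
Mean log2 CPM over the members of 11 gene lists in each library, with control Wistar in blue, diabetic GK in red, a marker shape per replicate number and a line at the group mean (n = 4 per group). Skeletal muscle genes stand out in GK 9, and the mean of the elastic fibre list is 7.26 in controls and 5.88 in GK.

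Camera called the adipocyte, glycolysis, fatty acid oxidation and nuclear-encoded respiratory chain lists higher in GK. Of 10 brown adipocyte genes 2 rose (3 adjusted over the list alone; median 1.25): Otop1, a proton channel, from 7.57 ± 3.37 to 78.6 ± 30.7 CPM, and Gk, glycerol kinase, from 60.2 ± 31.1 to 486 ± 246 CPM. Of 14 general adipocyte genes 4 rose (5 rose and 1 fell adjusted over the list alone; median 0.83), among them the lipid droplet genes Plin4 (1.09 ± 0.19) and Cidec (1.07 ± 0.25) and the glycerol channel Aqp7 (1.31 ± 0.28). In glycolysis 5 of 19 genes rose, 14 adjusted over the list alone, with a median of 1.12. The phosphofructokinase genes Pfkp and Pfkl changed by 2.33 ± 0.23 and 1.75 ± 0.38, and Pfkfb4, which makes their activator, by 2.41 ± 0.47. Camera gave adjusted p = 0.010 for brown adipocyte, 6.05e-04 for general adipocyte and 2.35e-05 for glycolysis genes, each with adjusted p = 0.716 with an estimated correlation. Fatty acid oxidation genes had a median of 1.04 with 1 of 21 higher, also adjusted over the list alone, the thioesterase Acot2 (2.17 ± 0.47; camera adjusted p = 0.00427, adjusted p = 0.732 with an estimated correlation; 8 higher and 2 lower without GK 9). None of 26 genes of the nuclear-encoded respiratory chain passed the test, over all genes or adjusted over the list alone. All 26 lay above 0 (median 0.54, camera adjusted p = 0.00522, adjusted p = 0.791 with an estimated correlation). Its most abundant genes were the ATP synthase genes Atp5b (2557 ± 1188 CPM in controls, 5424 ± 1975 in GK) and Atp5a1 (999.8 ± 477 and 1847 ± 686). For the 10 mitochondrially encoded genes, none past the test by either adjustment, the median was 0.12 (camera adjusted p = 0.672; with the fat score as a covariate -1.04 and 0.00155, a call), with Mt-co1 at 96408 ± 52234 CPM in controls and 147886 ± 61823 in GK, and Mt-nd1 at 12303 ± 6125 and 22551 ± 10337.

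Genes of lipid synthesis went both ways. Fasn, the fatty acid synthase, fell from 3181 ± 1893 to 326 ± 113 CPM (log2 fold change -3.29 ± 0.49, edgeR adjusted p = 0.0120), and Pnpla3, a lipid droplet hydrolase, from 114 ± 67.5 to 11.8 ± 7.19 CPM. Of 15 lipogenesis genes these and Scd1 fell and 1 rose, Gpam, the acyltransferase that starts glycerolipid synthesis (1.82 ± 0.40), a gene named after its value was seen. The list had 5 lower and 1 higher adjusted over the list alone (median -0.34, camera adjusted p = 0.305). Cholesterol synthesis and uptake had 2 of 19 genes higher (4 adjusted over the list alone; median 0.28). Hmgcs1, which makes HMG-CoA, went from 102 ± 23.2 to 434 ± 103 CPM and Lss, the lanosterol synthase, changed by 0.89 ± 0.14. The camera adjusted p of the list was 0.0351, with adjusted p = 0.716 with an estimated correlation. The call ended without control 9 (adjusted p = 0.0866), without GK 9 (0.430) and without both (0.543). Of 22 insulin signalling genes 1 fell, the receptor-binding inhibitor Grb14 (-1.33 ± 0.33), and none adjusted over the list alone (median 0.13, camera adjusted p = 0.672). With the fat score as a covariate the calls ended for glycolysis and fatty acid oxidation genes (adjusted p = 0.0661 and 0.0819). The adipocyte lists make up the score, so the loss of their calls under it decides nothing. The medians of fatty acid oxidation and nuclear-encoded respiratory chain genes then turned to -0.48 and -0.91, the last with adjusted p = 1.27e-11. The respiratory chain list also lost its call without control 9 (adjusted p = 0.154). Under the covariate 6 lipogenesis genes were lower (adjusted p = 1.72e-05), but without GK 9 the list had 3 higher and 3 lower (median -0.07, adjusted p = 0.95).

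Endothelial genes were higher. Of 17, 5 rose and none fell (6 rose adjusted over the list alone), with a median of 0.29. Kdr, the main receptor of vascular endothelial growth factor, went from 126 ± 23.0 to 343 ± 94.6 CPM, the transcription factor Sox17 from 15.2 ± 1.40 to 29.1 ± 5.80 and Nos3, the endothelial nitric oxide synthase, from 40.7 ± 7.90 to 69.7 ± 3.56. Camera gave adjusted p = 0.0104, with adjusted p = 0.716 with an estimated correlation. The call ended without control 8 (adjusted p = 0.0614) and without GK 9 (0.0836). It held without both libraries numbered 9 (0.0338) and with the fat score as a covariate (1.86e-04). Among 13 genes of nitric oxide and cGMP Nos3 rose and Arg1, an arginase that competes for its substrate, fell (-1.99 ± 0.34). Adjusted over the list alone 1 was higher and 3 lower (median -0.54, camera adjusted p = 0.0693; without GK 9 -0.97 and 0.0244, a call). Of 13 endothelin and prostanoid genes Ednrb, an endothelin receptor, rose from 10.1 ± 1.67 to 51.6 ± 32.1 CPM, and Ptgis, the prostacyclin synthase, fell by 1.65 on the log2 scale. Adjusted over the list alone 1 was higher and 3 were lower (median -0.04, camera adjusted p = 0.781). Ace, which makes angiotensin II, was the 1 of 10 renin-angiotensin-aldosterone genes to fall (-0.71 ± 0.13), against 2 higher and 3 lower adjusted over the list alone (median -0.44, camera adjusted p = 0.252). None of 22 genes of calcium and potassium handling passed the test by either adjustment (median -0.27, camera adjusted p = 0.0884, fry adjusted p = 0.0406), but 2 were higher and 6 lower without GK 9, over all genes. The most abundant were Itpr1, a calcium release channel (539 ± 43.2 CPM in controls, 822 ± 225 in GK), and Atp2a2, the calcium pump of the reticulum (468 ± 65.8 and 813 ± 302).

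Immune genes moved in different directions. At the major histocompatibility complex, whose RT1 genes present antigen, RT1-A1 rose from 20.7 ± 4.73 to 224 ± 35.1 CPM. RT1-A2 fell from 56.5 ± 19.2 to 8.05 ± 0.804 and RT1-Ba by 4.12 on the log2 scale (edgeR adjusted p = 8.95e-04, 0.00242 and 0.0114). In this list 1 of 20 genes rose and 4 fell, 1 and 5 adjusted over the list alone (median -0.16, camera adjusted p = 0.0668). RT1 genes are close relatives, so how reads were shared among them is uncertain. Complement genes were lower, with 4 of 14 down (6 adjusted over the list alone) and a median of -0.81. C4a went from 144 ± 58.2 to 18.0 ± 8.30 CPM and C3 from 17.5 ± 9.27 to 0.845 ± 0.790. Of 15 macrophage genes 1 fell (6 adjusted over the list alone), Lyz2, lysozyme (-1.45 ± 0.25; list median -0.92). Camera adjusted p-values were 3.31e-04 for complement and 6.05e-04 for macrophage genes, each with adjusted p = 0.716 with an estimated correlation. With the fat score as a covariate they were 0.671 and 0.453, and both calls ended. Interferon-stimulated genes had 3 of 26 higher, also adjusted over the list alone (median 0.68, camera adjusted p = 0.0693). Among them were Ifit1 and Ifi27 (1.97 ± 0.48), which reached 267 CPM in GK 10. The list's mean log2 CPM was 4.18 ± 1.17 in GK and 3.59 ± 0.228 in controls. The exact permutation p of the difference in means was 0.429, and the wider spread in GK was not tested. Of 21 inflammatory adhesion and cytokine genes 1 rose, Nfkbia, the inhibitor of NF-kappa-B (0.73 ± 0.17), and none adjusted over the list alone (median -0.21, camera adjusted p = 0.576).

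Lymphocyte and granulocyte genes gave no list call in the comparison of the 2 groups alone. Of 12 T cell genes none passed the test by either adjustment. Cd4 stood at 39.9 ± 17.0 CPM in controls and 16.0 ± 6.96 in GK and Lck, a T cell kinase, at 6.35 ± 1.73 and 7.41 ± 4.32. The T cell median of 0.02 and mean of 0.03 were above 0 while camera pointed down (adjusted p = 0.781). With the fat score as a covariate camera called the T cell list higher (median 0.81, adjusted p = 0.0180). None of 8 B and plasma cell genes passed by either adjustment (median -0.42, camera adjusted p = 0.216; without GK 9 -1.21 and 0.0367, a call), with Ighm, the heavy chain of IgM, at 38.3 ± 13.3 and 33.3 ± 18.0 CPM, and Igj, the joining chain, at 3.03 ± 1.98 and 3.67 ± 2.12. Of 7 neutrophil genes 1 fell, also adjusted over the list alone, the resistin-like gene Retnlg (-2.16 ± 0.45; list median -0.50, camera adjusted p = 0.225). None of 7 mast cell genes passed by either adjustment (median -1.29, camera adjusted p = 0.0693), with the protease Mcpt1 at 56.5 ± 30.4 and 23.1 ± 14.9 CPM and the receptor Kit at 17.4 ± 5.18 and 12.8 ± 4.70.

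Single stress, clock and growth genes changed without a call of their list in the comparison of the 2 groups alone. Nr4a3 and Nr4a2, early-response nuclear receptors, rose from 15.9 ± 7.73 to 188 ± 86.3 and from 11.6 ± 5.12 to 62.9 ± 56.4 CPM. Nr4a2 stood at 147 CPM in GK 10 against 40.4 or less in the other GK libraries. Gadd45b, a growth arrest gene, fell (-1.46 ± 0.27). In all, 2 of 23 immediate early and heat shock genes rose and 1 fell (3 and 2 adjusted over the list alone; median 0.37, camera adjusted p = 0.166). With the fat score as a covariate the list was called higher (median 1.80, adjusted p = 4.84e-04). Npas2, a partner of the clock protein Bmal1, fell from 62.4 ± 20.8 to 7.80 ± 2.05 CPM (edgeR adjusted p = 0.00294), and the clock repressors Per1 (1.02 ± 0.20) and Nfil3 (1.20 ± 0.28) rose. The circadian clock list had 2 of 18 higher and 2 lower (4 and 2 adjusted over the list alone). Its median of 0.11 and camera's direction (adjusted p = 0.545) were above 0 but its mean of -0.07 below. Among 11 glucocorticoid-responsive genes the kinase Sgk1 rose (1.21 ± 0.26; 1 higher and 2 lower adjusted over the list alone). The list had a median of 0.15 but a mean of -0.11 and camera pointing down (adjusted p = 0.717). Of 11 hypoxia genes Egln3, an oxygen-sensing hydroxylase, rose (1.41 ± 0.35; 3 higher adjusted over the list alone; median 0.20, camera adjusted p = 0.192). Of 23 genes of oxidative stress and NADPH oxidase 2 rose and 2 fell, 5 and 3 adjusted over the list alone (median 0.48, camera adjusted p = 0.216; without GK 9 0.69 and 0.0244, a call). Nqo1, a quinone reductase, was higher (1.76 ± 0.24) and the peroxidase Gpx3 (-1.22 ± 0.23) and the oxidase subunit Ncf1 (-1.30 ± 0.31) were lower. None of 17 unfolded protein response genes passed by either adjustment (median -0.03, camera adjusted p = 0.594). The chaperones Calr and Hspa5 stood at 397 ± 53.5 and 326 ± 57.9 CPM in controls and at 444 ± 35.9 and 444 ± 80.1 in GK.

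Cell cycle and ribosomal protein genes were lower. Of 22 cell cycle genes 3 fell (4 adjusted over the list alone). Mki67, a marker of dividing cells, went from 12.6 ± 3.75 to 5.99 ± 1.06 CPM, Cenpf of the kinetochore from 3.90 ± 1.19 to 1.27 ± 0.540, and the replication helicase gene Mcm7 from 25.2 ± 1.93 to 16.8 ± 1.97. Of 24 cytosolic ribosomal protein genes 2 fell (4 adjusted over the list alone), Rps18 (-2.77 ± 0.34) and Rpl7 (-0.71 ± 0.18). Rps18 had only 7.49 ± 2.18 CPM in controls and 1.09 ± 0.345 in GK, against 307 ± 62.8 and 187 ± 16.9 for Rpl7. It lies on chromosome 20 (5442390 to 5445509) near RT1-A1 (5351605 to 5421098), and how its reads were placed was not tested. The medians of the cell cycle and ribosomal lists were -0.43 and -0.44 and their camera adjusted p-values 0.00206 and 1.65e-04. With an estimated correlation each had adjusted p = 0.716. The cell cycle call ended with the fat score as a covariate (adjusted p = 0.579).

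Marker genes of other tissues differed between libraries. GK 9 held 8299 CPM of Myh1, a myosin of fast skeletal muscle, and 4313 CPM of Acta1, skeletal actin, against 3.73 and 9.08 or less in the other GK libraries. None of 7 skeletal muscle genes passed the test (4 rose adjusted over the list alone). Their median of 5.56 was -0.29 without GK 9 (camera adjusted p = 0.138 with all libraries). Mbp, a myelin gene, rose from 51.5 ± 9.99 to 134 ± 36.4 CPM, the 1 of 10 nerve and Schwann cell genes to pass by either adjustment. The list median of 1.69 (camera adjusted p = 0.0642) was 0.37 without GK 9 (adjusted p = 0.654). With the fat score as a covariate camera called both lists higher, skeletal muscle with a median of 6.61 (adjusted p = 0.00354) and nerve and Schwann cell genes with 3.23 and 8 of 10 higher (adjusted p = 1.72e-05). Mesothelial and epithelial genes had a median of -2.15, with none of 9 past the test (2 lower adjusted over the list alone) and a camera adjusted p of 0.0416 (adjusted p = 0.736 with an estimated correlation). That call ended without control 7, control 10, GK 9 or GK 10 (adjusted p = 0.145, 0.119, 0.127 and 0.195) and with the fat score as a covariate (0.265), without both libraries numbered 9 (0.0513), without mitochondrial genes (0.0633) and with the replicate number as a block (0.0541). Its most abundant genes were Msln, mesothelin (25.3 ± 30.9 CPM in controls, 4.10 ± 5.16 in GK), and the mucin Muc16 (13.2 ± 15.1 and 2.98 ± 3.61). Of the lists without a call or a changed gene, by either adjustment, erythroid genes had a median of -1.11 over 6 genes (camera adjusted p = 0.567). The haemoglobin genes Hba1 and Hbb stood at 10273 ± 10237 and 4389 ± 1272 CPM and at 2838 ± 3028 and 1615 ± 563. Lymphatic endothelial genes had a median of -0.27 over 7 (camera adjusted p = 0.548), and of -1.22 without GK 9 (0.178). In GK 9 they averaged 5.45 on the log2 CPM scale against 2.91 to 3.91 in the other GK libraries, and with the fat score as a covariate camera called them higher (median 1.53, adjusted p = 0.00401). Mmrn1 stood at 54.3 ± 37.0 and 45.0 ± 43.9 CPM and Lyve1, a hyaluronan receptor, at 50.9 ± 28.5 and 30.6 ± 15.1. Cardiomyocyte and sex-linked genes had 4 tested members each, too few for the list test, and medians of 2.61 and -0.01. Myh6, a cardiac myosin, stood at 79.7 ± 159 and 402 ± 513 CPM, the calcium channel Ryr2 at 139 ± 16.6 and 150.3 ± 121, and the Y-linked Ddx3y and Kdm5d at 67.8 ± 12.1 and 58.9 ± 6.77 in controls and 79.2 ± 10.6 and 59.5 ± 5.15 in GK.

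Of 44 lists tested by camera, 17 moved at a preset correlation of 0.01, 7 up and 10 down. Members past the test were more numerous without GK 9 in 36 of the 46 lists. With an estimated correlation 0 lists moved, and none had an unadjusted p under 0.05; fry called 2, glycolysis and calcium and potassium handling. With 4 against 4 libraries the exact permutation test of a list's mean cannot go below p = 0.0286. It gave 0.0286 for elastic fibre, glycolysis, complement, cytosolic ribosomal protein, renin-angiotensin-aldosterone and histocompatibility genes. Of these, camera did not call the renin-angiotensin-aldosterone and histocompatibility lists. Among others, fibroblast genes had an exact permutation p of 0.0571, and collagen and contractile smooth muscle genes 0.0857. Adjusted over the lists, the p of this test was 0.202 or more for every list.

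**Figure D3:**
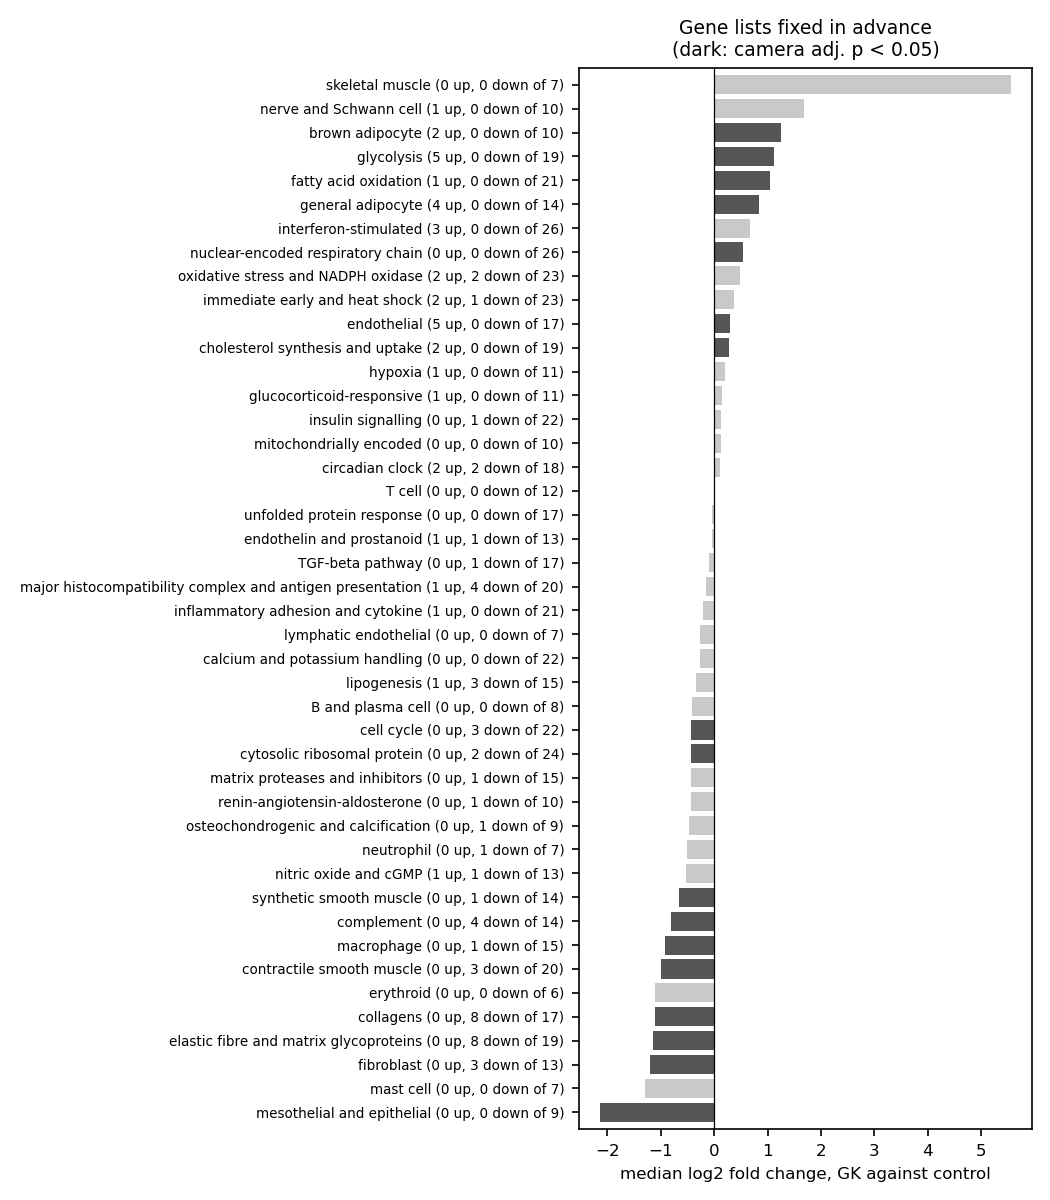
Median log2 fold change (GK over control) of 44 gene lists, with the members that rose and fell by edgeR in brackets and dark bars where camera's adjusted p was under 0.05 at the preset correlation. The bars run from -2.15 for mesothelial and epithelial genes to 5.56 for skeletal muscle genes, whose median was -0.29 without GK 9.

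Whether lncRNAs differ between the strains was the second question. The 10 named transcripts all had 0 counts in one group, so their folds are lower bounds from a floor of 3 counts over the group. Bounds and intervals cover counting error only. MSTRG.18616.7 (chromosome 18, 56682364 to 56699148), which overlaps Ppargc1b, a coactivator of mitochondrial genes, was at least 2908-fold higher in GK, at 1289 ± 634 CPM of the lncRNA table (edgeR adjusted p = 0.00357). MSTRG.8782.2 (chromosome 11, 64611601 to 64624560), in Arhgap31, a gene of a GTPase-activating protein, was at least 693-fold higher, at 307 ± 208 CPM. MSTRG.37469.2 in Trps1, a transcription repressor, MSTRG.28194.14 in Ptpn12, a tyrosine phosphatase, and MSTRG.21075.4 in Slc1a3, a glutamate transporter, were at least 258-fold, 251-fold and 248-fold higher, with most of each mean from 1 library (272 CPM in GK 8, 276 in GK 9 and 237 in GK 7). On the other side, MSTRG.21616.2 (chromosome 2, 117602507 to 117614557) was at least 714-fold lower in GK, from 327 ± 243 CPM in controls, and MSTRG.14002.23 (chromosome 15, 13431924 to 13452130) at least 585-fold lower, from 268 ± 196 CPM. MSTRG.83.1 in Sash1, MSTRG.32978.33 and NONRATT026294.2 in Dazap2 were at least 178-fold, 125-fold and 108-fold lower. The overlapping genes had small log2 fold changes: Ppargc1b 0.40, Arhgap31 0.44, Ptpn12 0.2, Trps1 -0.75, Slc1a3 -0.36, Sash1 -0.42 and Dazap2 -0.24. The bounds are therefore of single transcripts and not of these loci. Isoforms and genes overlap here and the strandedness of the libraries is not given in the sources used here, so which transcript the reads came from is uncertain.

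In all, edgeR called 320 of 11683 lncRNAs tested, 190 higher and 130 lower in GK. The groups did not overlap for 1365, 11.7% against 2.86% expected by chance, and for 319 of the 320. Transcripts are not independent, so this excess by itself does not exclude chance. Of the calls, 25 had 0 counts in one group, 15 in the controls and 10 in GK. With the library totals and factors of the gene table the count was 322, but 158 were higher and 164 lower, so the share that was higher moved from 59.4% to 49.1%. Without a single library the lncRNA count was 108 (GK 7), 111 (GK 8), 120 (control 10), 143 (GK 10), 165 (control 8), 206 (control 7) and 581 (GK 9), and with the fat score as a covariate it was 93.

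Whether lncRNAs move with their predicted target genes was asked from the authors' list of 17441 pairs. The pairs with the lowest adjusted p lay at Dmp1, a mineralisation gene of bone and dentin. MSTRG.12320.1 and MSTRG.12319.8 changed by -2.79 ± 0.24 and -2.56 ± 0.32 on the log2 scale, and Dmp1 on chromosome 14 (6889856 to 6900733) by -2.85 ± 0.28. NONRATT009921.2 changed by -7.58 ± 0.59 and the gene Rn60_14_0474.1, whose span covers it, by -3.84 ± 0.48. MSTRG.23736.1 and NONRATT001106.2 fell (-5.27 ± 0.52 and -2.54 ± 0.25) while their trans target Myo18a, an unconventional myosin, rose (1.25 ± 0.16). In 432 pairs both members changed, 81 lncRNAs and 93 genes, and 55.6% had the same sign against 49.7% with lncRNA fold changes permuted (permutation p = 1e-05, two-sided, the smallest the permutations can give). Pairs listed as cis gave 96.2% of 53 (permutation p = 1e-05), and those listed as trans 49.9% of 379 (p = 0.604). In 35 of the 53 cis pairs the spans of lncRNA and gene overlap, where shared reads alone would give the same sign. The other 18, with 17 genes, all had the same sign (permutation p = 8e-05), but some of these spans nearly touch. Nr4a3 ended at 63821637 and NONRATT022258.2 began at 63821761 on chromosome 5. On chromosome 14 NONRATT009912.2 ended at 45982041 and Rell1 began at 45982244. Reads of 1 transcript counted for both members were therefore not excluded here either. Without the overlapping pairs, left out after the data were seen, the share over all kinds was 52.1% of 397 (permutation p = 0.0207). Over all 6309 tested pairs the share was 51.7% against 50.6% by permutation (p = 0.0258). The share of changed pairs over all kinds was 57.1% without control 10 (permutation p = 0.511) and 47.7% without GK 8 (p = 1), where the call ended, and with the fat score as a covariate 53.2% (p = 0.171).

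The authors' deposited table called 1039 genes, 562 higher and 477 lower, and 541 of these (52.1%) were among the 995, all 541 in the same direction. For lncRNAs the authors' deposited table called 763, 470 higher and 293 lower, of which 233 (30.5%) were among the 320, all in the same direction. Only 364 of the 763 and 869 of the 1039 in the authors' deposited table passed the count filter here. Of the authors' calls, 60 genes and 217 lncRNAs had an infinite fold in the authors' deposited table, a group mean of 0. Both sets of calls rest on the same libraries, so their overlap is no independent evidence. Extracellular matrix led the authors' deposited table of gene ontology terms with 71 genes, 8 higher and 63 lower (adjusted p = 2.72e-18). Next in the authors' deposited table came extracellular region (294 genes, 5.39e-15), proteinaceous extracellular matrix (54, 7.45e-14), vesicle (238, 1.98e-11) and monocarboxylic acid metabolic process (68 genes, 43 of them higher, 4.63e-11), and in all 507 of 2114 terms were under 0.05. In the authors' deposited table of KEGG pathways 21 of 261 were under 0.05, led by Protein digestion and absorption (20 genes, 3.91e-05) and Arachidonic acid metabolism (15 genes, 13 of them lower, 0.00238). By adjusted p ECM-receptor interaction (12 genes, 0.0202), Salivary secretion (11, 0.0204) and Arginine and proline metabolism (9, 0.0210) followed in the authors' deposited table. Their unadjusted p-values in the authors' deposited table were 0.00108, 0.00117 and 0.00105, so the order by unadjusted p differs.

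For called genes that are lncRNA targets, the authors' deposited table was led by muscle system process (14 genes, adjusted p = 0.000228), triglyceride biosynthetic process (5, 0.000801), contractile fiber (9, 0.00346), multicellular organism metabolic process (6, 0.00378) and muscle contraction (10, 0.00428). Under 0.05 in the authors' deposited table were 25 of 606 terms. No pathway of that set was under 0.05 in the authors' deposited table (41 of 162 at an unadjusted p under 0.05). By adjusted p Insulin signaling pathway came first in the authors' deposited table (5 genes, 0.0567). Its unadjusted p there was 0.00350, while the lowest unadjusted p of the set was 0.000554. Next by adjusted p came Glucagon signaling pathway and GnRH signaling pathway (4 genes each, 0.0665), Allograft rejection (3, 0.0705) and Graft-versus-host disease (3, 0.0707). Over all predicted targets the authors' deposited table began, by adjusted p, with carbohydrate derivative binding (157 genes, 0.00320) and ion binding (349, 0.00338). Next in the authors' deposited table came nucleotide binding (167, 0.00362), adenyl nucleotide binding (112, 0.00448) and anion binding (183, 0.00455). The lowest unadjusted p in the authors' deposited table, 1.07e-06, belonged to none of these terms. Of 2178 terms 14 were under 0.05 in the authors' deposited table. Pathways of all targets in the authors' deposited table had none under 0.05 (45 of 274 unadjusted). By adjusted p the authors' deposited table began with Tuberculosis (22 genes, 0.0681) and Carbohydrate digestion and absorption (6, 0.190). Antigen processing and presentation (10, 0.195), VEGF signaling pathway (8, 0.197) and Fatty acid degradation (7, 0.199) came next in the authors' deposited table. The order by unadjusted p differs, with 0.0153 for Carbohydrate digestion and absorption and 0.00994 for Antigen processing and presentation. Parental genes of changed circular RNAs, per the authors' deposited table, had 1 of 21 pathways under 0.05, Drug metabolism - other enzymes (2 genes, 0.00662), ahead of Metabolic pathways (4 genes) and, with 1 gene each, the Neurotrophin and Wnt signaling pathways and Nicotinate and nicotinamide metabolism. Gene ontology terms of these parents in the authors' deposited table had none under 0.05 (38 of 193 unadjusted). First in the authors' deposited table were peptidyl-lysine modification (5 genes, 0.204), ubiquitin ligase complex (4, 0.212), histone modification (5, 0.220), ubiquitin-like protein transferase activity (5, 0.263) and ubiquitin-protein transferase activity (5, 0.277). Where the parental gene itself was called, 0 of 10 terms in the authors' deposited table passed (3 unadjusted). The authors' deposited table put metal ion binding (4 of 7 genes), cation binding (4), ion binding (5), regulation of cellular process (5) and membrane (4) first, each with an adjusted p of 1.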

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

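Tests chosen only after the result was seen were the one of a lower share of smooth muscle and fibroblasts, the one of a smaller share of fat, and both tests of the histocompatibility genes. The fat score was added as a covariate after the data were seen, but the test that uses it here was set before its result was.

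Genes of the matrix were lower in GK. Tissue from skeletal muscle and nerve in GK 9 is argued against, since without GK 9 the median log2 fold change of the 36 collagen and elastic fibre genes was -1.55, against -1.13 with it, and 25 genes fell and 1 rose, against 16 falls with it, all 16 of them among the 25. A larger share of perivascular fat in the GK libraries cannot be told apart from a change in the wall, because with the fat score as a covariate the group difference was -0.37 (95% interval -1.12 to 0.37), against -1.26 (-2.15 to -0.37) without it, and 5 of the 16 falls were kept, with 3 genes then called higher, as the effect shrank and its interval included 0. A lower share of smooth muscle and fibroblasts may account for it, but the test made cannot decide this. The matrix genes minus the smooth muscle and fibroblast genes differed by -0.13 (-0.47 to 0.20, exact p = 0.343, n = 4 per group). The fibroblast list itself holds matrix genes such as Dcn, Lum and Dpt, so a lower output per cell could also give a small difference. A lower output of matrix per cell in the diabetic strain stays open and was not tested.

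Fasn and Pnpla3 were lower in GK. A smaller share of fat is argued against, since the general adipocyte genes had a median log2 fold change of 0.83 (interval of the group difference in their mean 0.17 to 1.16). Fasting before collection stays open. A difference in lipid synthesis that belongs to the strain or to diabetes stays open, as untested.

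Histocompatibility genes moved apart. Fewer antigen-presenting cells alone would lower the 8 class II genes of the list alike, but these ran from -4.12 to 0.29 on the log2 scale. The SD of their group differences was 1.47 (exact p = 0.0286, n = 4 per group, the smallest the design allows). RT1-Ba, already named for its fall, is among the 8, so that p adds little. The spread argues against fewer cells as the whole cause only. Strain variants would give it at any number of cells, and 14 of 15 macrophage genes lay lower and 1 higher (median -0.92). Fewer antigen-presenting cells in part therefore stay open. Strain variants against the reference sequence are a candidate explanation: class I genes ran from -4.51 to 3.44, while B2m, Tap1, Tap2, Tapbp, Psmb8 and Psmb9 had a median absolute log2 fold change of 0.0820. A true difference in which RT1 genes the strains express stays open, as untested.

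A library far from the other 3 of its group was looked for by Dixon's ratio, the gap to the nearest library over the range of the group. It passed in 29 of 248 groups of 4; chance flags about 1 in 20 groups, here 12.4, and 14 of the 29 were in GK 9. The lowest or highest value in GK 9 stood apart for Tmem179 (0.877), Cacna1b (0.901), Scd1 (0.995), RT1-Ba (0.871), Myh1 (0.9997, at 8299 CPM), Acta1 (0.999), Mmrn1 (0.931), Lss (0.887) and RT1-A2 (0.861), all high, and for Ddx3y (0.958), Pfkfb4 (0.835), Itpr1 (0.915), Atp5a1 (0.982) and the fat score (0.943), all low. In GK 10 Ifit1 (0.923), Ifi27 (0.896) and Nr4a2 (0.904) were high, in GK 7 Mfsd2a (0.890) was high, and in GK 8 Hba1 (0.841) was low. Among controls, Slc16a14 (0.860), Crabp2 (0.858), Lyz2 (0.891) and Mfsd2a (1, the others at 0) were high in control 9. In control 8 Orm1 (1, the others at 0) and Myh1 (0.982) were high and Mcpt1 (0.883) low, and in control 7 Ush1c (0.923) and Myh6 (0.998) were high and Sparc (0.902) low.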

How the results depend on the processing

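Leaving out both libraries numbered 9, mitochondrial genes or overlapping pairs, and the fat score as a covariate, were chosen after the data were seen; the other settings were planned. The count of changed genes, 995, was 2433 by the DESeq2 Wald test (991 of the 995 among them), 1644 by edgeR's exact test (968), 654 without a filter (629), 631 with a 2-fold minimum, 2372 with the replicate number as a block (968) and 2532 without both libraries numbered 9 (947). Leaving out each library gave 135 to 3047. With DESeq2 size factors (983), a mean CPM of at least 1 (856), sums per symbol (993), no mitochondrial genes (968) and the fat score as a covariate (1323) it stayed within 1.5 times, though 345 of the 995 were among the 1323. The block was run as an alternative only, since the libraries share no more than a number, their deviations from the group mean correlated across genes at 0.42, 0.07, 0.55 and 0.02 for numbers 7 to 10, genes not being independent replicates, and 4 of 8 libraries matched their own number best.

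The lncRNA count, 320, was 931 by the DESeq2 Wald test, 681 by edgeR's exact test, 158 without a filter, 177 at a mean CPM of at least 1, which let 19513 transcripts into the test, 250 with the replicate number as a block (175 shared), 503 without both libraries numbered 9 and 93 with the fat score as a covariate (52 shared). Leaving out each library gave 108 to 581. The cause was not tested, except that settings with more transcripts or fewer libraries differ in what they test.

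Of 44 lists 17 were called as reported, 0 with an estimated correlation, 2 by fry, 11 with the fat score as a covariate and 21 with the replicate number as a block, and 17 to 22 when each library was left out. With the block 16 of the 17 kept their call, and mesothelial and epithelial genes lost it (median -1.83, adjusted p = 0.0541). With the covariate 3 of the 17 lists kept their call, 10 lost it, and camera's direction turned for 4. The medians turned to -0.53 for brown adipocyte, -0.48 for fatty acid oxidation and -0.91 for nuclear-encoded respiratory chain genes, while that of synthetic smooth muscle genes stayed below 0 (-0.19); the brown and general adipocyte lists make up the covariate, so their lost calls decide nothing, and for the others the cause was not tested. The share of pairs with the same sign, 55.6%, was 49.9% for trans pairs, 52.1% without pairs whose spans overlap and 53.2% with the covariate, and 47.7% to 73.9% when each library was left out; the cause was not tested.

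Of 82 named genes called, 81 kept their call with DESeq2 size factors, 81 of 81 tested by the DESeq2 Wald test, 80 with the replicate number as a block, 80 without both libraries numbered 9, 39 with the fat score as a covariate, and 27 (without control 10) to 82 (without GK 9) when a library was left out, none in the opposite direction. Small changes were often missed in the simulated data, 19 of 100 genes being recovered at 2-fold; whether depth or the number of libraries sets this was not tested. Sums per symbol for lncRNA and pseudocounts were not run: the lncRNA table pairs no symbols with its transcripts, and counts were used, not normalised values.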

Other observations

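The test of neighbouring genes and the splits of the libraries were planned before their results were seen; the genes in the next paragraph were chosen after their values were seen.

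Changed genes outside the lists were of mixed kinds. Syn2, a synaptic vesicle protein, rose from 1.73 ± 0.350 to 38.0 ± 19.8 CPM, and the potassium channel gene Kcnh1 from 0.688 ± 0.207 to 10.4 ± 3.55 (means ± SD, n = 4 per group). Atp1b1, a subunit of the sodium pump, rose from 17.6 ± 4.16 to 101 ± 19.8 CPM and the tubulin gene Tuba4a from 16.2 ± 5.34 to 106 ± 5.54. Ndn, an imprinted gene beside Magel2 on chromosome 1, rose from 7.90 ± 1.39 to 127 ± 57.0 CPM. Tbx18, a transcription factor of mural cells, fell from 30.5 ± 2.06 to 12.7 ± 1.03 CPM, and the collagen gene Col7a1, outside the collagen list, rose from 12.2 ± 4.49 to 87.8 ± 23.6. Atp4a, the gastric proton pump, had 0 counts in the controls and was at least 52.3-fold higher in GK (floor of 3 counts over the group).

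Changed genes lay next to each other. Of neighbouring tested genes, 63 pairs were both changed in the same direction, against 36.4 on average and 25 to 48 in 95% of 10000 random placements (permutation p = 1e-04, the smallest they can give), and 62 against 34.9 where the genes do not overlap. Haplotype blocks that differ between the strains may account for this, but shared regulation of neighbours would give the same count and was not tested. Runs of 3 included Lzts1, Atp6v1b2 and Lpl on chromosome 16 (higher), and RT1-Bb, RT1-Ba and RT1-Db1 on chromosome 20 (lower).

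Among the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many as 320 lncRNA calls. The highest other split gave 5. A share of 1 in 35 is the smallest these splits can give, so chance is unlikely but not excluded for that count. For genes, 2 splits gave as many as the real 995, and the highest other gave 1489, so chance is not excluded; that split exchanges GK 9 and control 8 between the groups and points to a structure of the samples beside the group. For lists, 20 splits gave at least the real 17, and the highest other gave 25, so chance is not excluded. The first principal component of log2 CPM held 43.5% of the variance and the second 26.3%; GK 9 stood at -20.2 on the first, where the other GK libraries lay between 51.2 and 64.3, and the controls between -68.3 and -14.0.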
